A study of Mus musculus with 18 samples.

How the data were processed

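The study measured messenger RNA in left and right atria of mice that the labels call WT, Het and KO for Zfhx3, with 18 samples from 9 animals by the IDs in the sample titles. Per the labels' protocols, RNA was isolated with the Direct-zol RNA Miniprep kit, libraries were made with an mRNA enrichment method (KAPA mRNA HyperPrep) and sequenced on an Illumina NovaSeq. The authors deposited a table of gene counts, which holds whole numbers and was read as raw counts. The submitters' processing notes name STAR 2.7.9a, DESeq2 1.30.1 and the mm10 genome, without saying which tool did the counting. The annotation release, the counting rule and the strand used are not given in the sources used here. The labels name no batch, and the sex of the animals is not given.

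The table has 56691 gene IDs, of which 52073 were matched by base ID to a symbol in GENCODE M21 (GRCm38), and 35 also by ID version. IDs without a match held 0.418 to 2.63% of the counts of a library, and no column was left unused. Most of this share was 1 ID that resembles 18S ribosomal RNA, with more of the counts in every WT library (1.59 to 2.52%) than in any Het or KO library (0.287 to 1.49%). WT RA replicates 1 and 2 have identical counts for every gene, and which of the animals they come from is unknown. They were counted as 1 library, so 17 libraries were analysed, 9 in LA and 8 in RA. The design had been written for 9 libraries in each atrium, and the tests were kept as written with 1 library less.

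Each comparison used edgeR 4.0.16 in R 4.3.3, with filterByExpr at a minimum count of 10, TMM scaling, robust quasi-likelihood fits and F tests. Benjamini-Hochberg adjusted p under 0.05 counts as called, and "edgeR adjusted p" in the report means this value. The genotype comparisons used the libraries of all 3 genotypes in 1 atrium, and the atrium comparison and the interactions used all 17. CPM values carry TMM scaling, log2 levels of libraries use a prior count of 2, and ± gives the SD between libraries. Library depth ran from 18000583 counts in WT LA replicate 3 to 33483085 in KO LA replicate 3, so that weakly expressed genes are measured least precisely in WT LA replicate 3.

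Genes were named by a rule. It takes Zfhx3, then the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM, a proper gene symbol and no overlap between the groups' libraries. It adds the 2 called members with the smallest p from each list with 3 or more called members, for at most 10 lists. A few genes that the rule picks are not reported. Other members stand as examples. The 38 gene lists were written from general knowledge of the heart and cover chambers, ion channels, contraction, signalling, metabolism, stress and cell types. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. The list of lung epithelial markers had under 3 expressed members and was not tested, which leaves 37. Counts "adjusted over the list alone" adjust p over the members of 1 list. Sex-linked genes were set apart.

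The design, the lists and most alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no filter on low counts, each library left out in turn, only the genotypes compared, all libraries in 1 fit, the replicate number as a block and Xist as a covariate. Added once the data had been examined were the identical columns as 2 libraries, offsets for GC content and transcript length, and the block with the identical library as WT animal 2. Where a left-out library leaves 1 WT RA library, that library is assumed to vary like the other groups. LA and RA libraries of the same number come from the same animal by the title IDs, and their deviations from the group means correlated at 0.158 to 0.411, so the animal block stands beside the atrium results. List medians were also compared under 4 scalings as differences of mean log2 CPM.

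Mitochondrial genes were searched with blastn 2.17.0 for nuclear copies among the annotated transcripts of GENCODE M21. A copy of at least 99% identity over 90% of the gene counts as near-identical. mt-Nd4, with a copy of 100% identity over 63.6% of the gene, and mt-Atp8 were placed in neither group. No copy of mt-Atp8 was found. Both of its neighbours have near-identical copies on chromosome 1, and its own copy there may have no annotated transcript. Calls and fold changes shared between KO and Het were set beside 20 simulations of unchanged groups that share the WT libraries. The edgeR test was also tested on simulated data with 200 changed genes in 5 runs. In KO against WT it recovered 35.2, 64.5 and 88.5% of genes changed 1.5, 2 and 4-fold in LA with 9.8 false calls per run, and 39.4, 69.9 and 87% in RA with 13.8. Between WT atria it recovered 36.1, 57.9 and 81.8% with 6.8 false calls. A list of 50 genes set 1.3-fold lower was called in 5 of 5 runs and an unchanged list in 0. Genes were simulated independently of each other, so these runs cannot test the preset correlation used in camera. Exon-level reads, sequence variants and splicing were not analysed here.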

Results

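Messenger RNA was sequenced from the left atrium (LA) and right atrium (RA) of mice in 3 genotype groups, which the labels call WT, Het and KO for Zfhx3. Zfhx3 encodes a zinc finger homeobox transcription factor, and its human counterpart lies at a known atrial fibrillation locus. The sample titles name 9 animals, 3 of each genotype, and each animal gave 1 LA and 1 RA library, so replicates within an atrium are separate animals. The columns of WT RA replicates 1 and 2 held identical counts for every gene. They were counted as 1 library. This leaves n = 2 for WT RA, n = 3 for each other group and 17 libraries in all. Total counts in LA were 23556281, 30329736 and 18000583 for WT replicates 1, 2 and 3, 28709004, 26350311 and 19067999 for Het, and 27965425, 30484199 and 33483085 for KO. In RA they were 23200510 for the WT library of replicates 1 and 2 and 22394892 for replicate 3, 24986974, 25510614 and 32807452 for Het, and 21771041, 28904493 and 29552912 for KO.

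Genes of the sex chromosomes divided the animals unevenly between genotypes. All WT libraries had Xist, the RNA of the inactive X chromosome, at 0.722 to 1.12 CPM and Y-linked Ddx3y at 111 to 151 CPM. All Het libraries had Xist at 608 to 741 CPM and no Ddx3y count. KO replicate 1 had the same pattern as Het, with Xist at 725 CPM in LA and 799 CPM in RA, while KO replicates 2 and 3 had Ddx3y at 145 to 166 CPM. The WT animals therefore showed a male pattern, the Het animals a female pattern and the KO animals both. The comparison of Het with WT alone thus cannot tell genotype from sex. The labels give no batch or collection day.

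Zfhx3 itself (ENSMUSG00000038872.11, chromosome 8, 107942644 to 108961630, plus strand, GRCm38) was counted at similar levels in every library. In LA its counts were 383, 473 and 215 in WT, 577, 455 and 346 in Het, and 502, 525 and 494 in KO. In RA they were 480 and 391 in WT, 517, 539 and 605 in Het, and 409, 439 and 521 in KO. KO left atria held 16.1 ± 1.09 CPM and WT left atria 16.1 ± 2.08 CPM (SD, n = 3 each; log2 fold change 0.00, SE 0.11, edgeR adjusted p = 0.99). KO right atria held 17.5 ± 1.79 against 19.6 ± 1.79 CPM in WT (n = 3 and 2; log2 -0.17, edgeR adjusted p = 0.50). Het values were 17.3 ± 1.54 CPM in LA (log2 0.10, edgeR adjusted p = 0.60) and 19.4 ± 1.17 CPM in RA (log2 -0.02, edgeR adjusted p = 0.97). No alternative analysis called Zfhx3 in these comparisons. The labels do not say which part of the gene was altered or in which cells, so a count over the whole gene may not show the alteration and does not check the genotype labels.

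**Figure D1:**
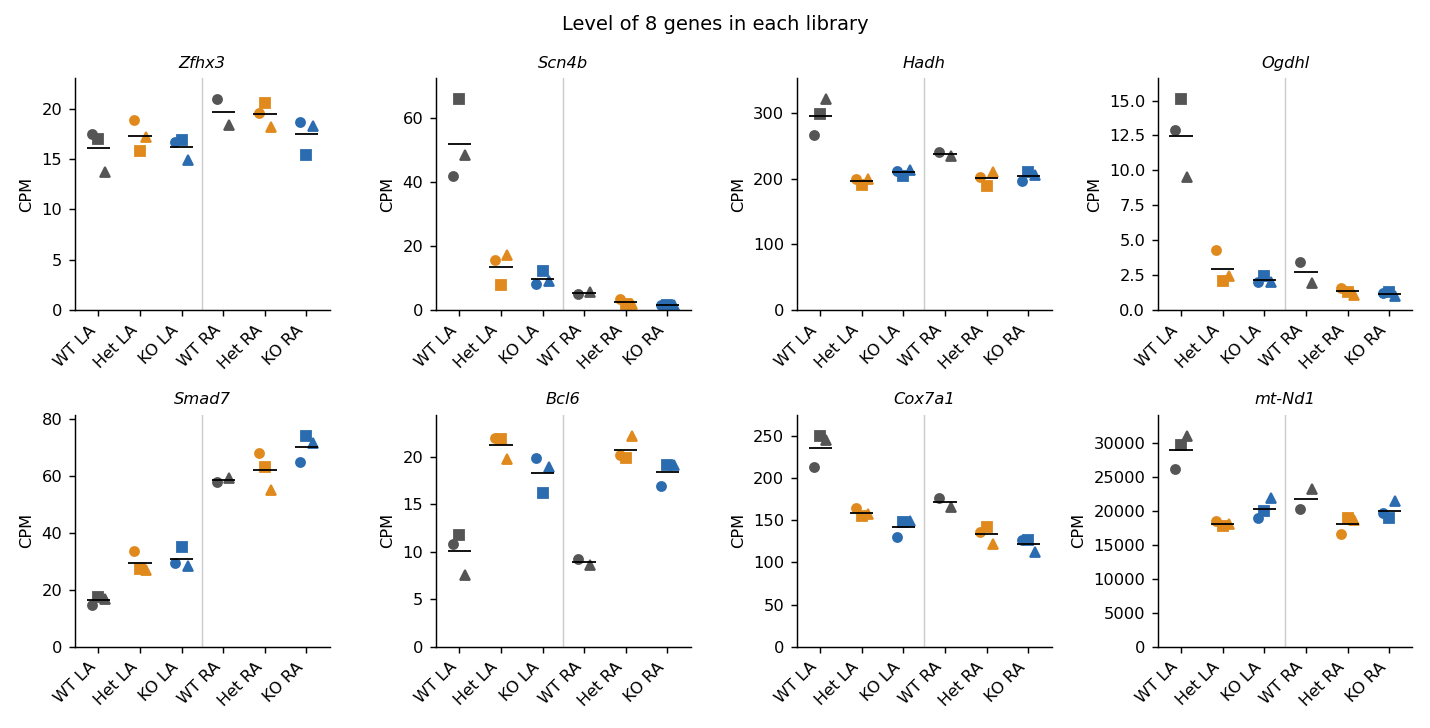
CPM (linear axis from 0) of 8 genes in each library, grouped by genotype and atrium, with 1 point per library and a bar at the group mean. Zfhx3 has LA group means of 16.1 to 17.3 CPM, while Scn4b falls from a WT mean of 51.9 to 9.76 CPM in KO LA and Smad7 rises from 16.3 to 30.9 CPM.

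The series title ties loss of Zfhx3 to atrial dilation and arrhythmia, and the first comparison asked which genes differed between KO and WT left atria. Genes of energy metabolism and several ion channel genes were lower in KO, and some genes of TGF-beta and BMP signalling were higher. Scn4b (chromosome 9, 45138395 to 45154152), which encodes a beta subunit of voltage-gated sodium channels, fell from 51.9 ± 12.4 to 9.76 ± 2.2 CPM (log2 -2.41, SE 0.32, edgeR adjusted p = 0.012). Hcn2, a pacemaker channel gene, fell from 7.05 ± 1.06 to 2.65 ± 0.129 CPM (log2 -1.41, edgeR adjusted p = 0.00588). Ogdhl, an enzyme related to oxoglutarate dehydrogenase, fell from 12.5 ± 2.79 to 2.15 ± 0.247 CPM (log2 -2.54, SE 0.27, edgeR adjusted p = 0.0034). Smad7 (chromosome 18, 75367529 to 75395935), an inhibitor of TGF-beta signalling, rose from 16.3 ± 1.38 to 30.9 ± 3.64 CPM (log2 0.92, SE 0.11, edgeR adjusted p = 0.0052).

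In this comparison 1326 of 16974 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 581 higher and 745 lower in KO, and 157 of them by more than 2-fold. At an unadjusted p under 0.05 there were 4324. In all 1326 the KO and WT libraries did not overlap, which held for 30% of all tested genes and would hold for 10% by chance with 3 against 3. Without any scaling beyond library totals the median of all genes moved by 0.18 on the log2 scale and 91.3% of 2993 calls were higher, against 43.8% with TMM scaling, so each change is given relative to TMM. The count was 305 without WT LA replicate 2, 480 without WT LA replicate 3, 334 without KO LA replicate 1, 647 without KO LA replicate 2 and 249 without KO LA replicate 3. It was also 662 with the KO and WT libraries alone and 542 with Xist as a covariate, and it reached 2350 without a filter on low counts and 2016 with all libraries in the fit.

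Genes of the respiratory chain and of fatty acid oxidation fell together in KO left atria. Of 96 nuclear-encoded respiratory chain genes, 50 fell and none rose (75 fell and 2 rose adjusted over the list alone). The list had a median of -0.30 and a camera adjusted p = 1.77e-22, or adjusted p = 0.657 with an estimated correlation. Cox7a1, a heart and muscle subunit of cytochrome c oxidase, fell from 237 ± 19.7 to 142 ± 10.3 CPM (log2 -0.73, SE 0.08, edgeR adjusted p = 0.0034). Ndufb9, a complex I subunit, fell from 79.7 ± 9.62 to 51.2 ± 3.79 CPM (log2 -0.64, edgeR adjusted p = 0.0067). Of 24 fatty acid oxidation genes 13 fell and none rose (18 fell adjusted over the list alone). This list had a median of -0.52 and a camera adjusted p = 1.43e-08, or adjusted p = 0.657 with an estimated correlation. Hadhb, a subunit of the mitochondrial trifunctional protein, fell from 361 ± 26.3 to 242 ± 9.29 CPM (log2 -0.57, edgeR adjusted p = 0.0087), and Hadh from 296 ± 27.6 to 210 ± 4.86 CPM (log2 -0.49, edgeR adjusted p = 0.0087). Among 20 glycolysis genes Pfkp rose (log2 0.50) while Pdk1 (-0.30) and Ldhb (-0.34) fell. Adjusted over the list alone 1 rose and 13 fell, with a camera adjusted p = 0.00154 towards lower values, or adjusted p = 0.711 with an estimated correlation.

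Mitochondrially encoded genes also fell in KO left atria, 12 of 13 (12 adjusted over the list alone), with a camera adjusted p = 1.86e-11, or adjusted p = 0.621 with an estimated correlation. The 6 without a near-identical nuclear copy all fell, from -0.40 (mt-Nd2) to -0.76 (mt-Nd6) on the log2 scale, with edgeR adjusted p from 0.01 to 0.0488. mt-Nd1, for example, fell by 0.52 (edgeR adjusted p = 0.0164). mt-Nd4 (-0.55), which has a copy of part of its length, is not among the 6 and fell too. Larger fitted falls in mt-Co2 (-2.04), mt-Atp6 (-2.06) and mt-Co3 (-1.96) are uncertain, since these genes have near-identical nuclear copies and were counted at only 2.26, 1.62 and 1.96 CPM in KO. The mitochondrial share of all counts was 24.1, 25.1 and 26.7% in WT LA and 19.3, 19.8 and 22.3% in KO LA. Beside these groups, cardiomyocyte markers were lower in KO as well, at a mean of 11.03, 11.11 and 11.18 log2 CPM against 11.22, 11.28 and 11.45 in WT. Of 16 such markers 3 fell, Ckmt2, Pln and Nppa (6 adjusted over the list alone; camera adjusted p = 0.00539, or adjusted p = 0.711 with an estimated correlation). Without WT LA replicate 3 the lower calls were 19 in the respiratory chain, 4 in fatty acid oxidation and 8 among mitochondrially encoded genes.

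Changes in genes of excitation and calcium handling went in both directions. Of 11 sodium channel, pacemaker channel and connexin genes 3 fell, among them Scn4b and Hcn2 (also 3 adjusted over the list alone), with a camera adjusted p = 0.0234, or adjusted p = 0.621 with an estimated correlation. The connexin gene Gja5 was at 212 ± 58.2 against 208 ± 30 CPM (edgeR adjusted p = 0.94). Of 28 calcium handling genes 2 rose and 4 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.309). Pln, which encodes the calcium pump inhibitor phospholamban, fell from 909 ± 161 to 594 ± 51 CPM (log2 -0.61, edgeR adjusted p = 0.024). Camk2b (-0.69), the L-type channel gene Cacna1c (-0.44) and Hrc (-0.30) also fell, while the pump gene Atp2b4 (0.90) and Itpr1 (0.36) rose. Of 24 potassium channel genes 2 fell, such as Kcnj11 (-0.38), and Abcc9 (0.60, edgeR adjusted p = 0.03) rose (2 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.753). The sarcomere list had 1 of 26 genes lower, Tcap (-0.96; 3 adjusted over the list alone), with a median of -0.13 that turned to 0.05 without scaling, and a camera adjusted p = 0.0156, or adjusted p = 0.753 with an estimated correlation and 0.297 without WT LA replicate 3.

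Atrial identity and stress genes gave single changes. Nppa, the atrial natriuretic peptide gene, fell from 3790 ± 310 to 2650 ± 376 CPM (log2 -0.52, SE 0.12, edgeR adjusted p = 0.03), whereas Nppb, the B-type peptide gene, rose from 136 ± 27 to 285 ± 78.6 CPM (log2 1.07, edgeR adjusted p = 0.0343). Of 18 atrial chamber genes Hey1 (0.57) and Tbx5 (0.28) rose and Nppa fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.184). Among 13 left-right and pacemaker identity genes Vsnl1 (1.43) and Shox2 (1.17), a transcription factor of the sinus node, rose from low levels and 1 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.99). The transcription factors Gata6 (0.37, edgeR adjusted p = 0.024) and Tbx20 (0.39, edgeR adjusted p = 0.037) rose, so that 4 of 24 cardiac transcription factors were higher (4 adjusted over the list alone; camera adjusted p = 0.269). Of 34 genes at atrial fibrillation loci Phldb2 (0.54), Tbx5, Cav2 (0.26) and Sh3pxd2a (0.32) rose and Pln fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.99).

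In KO left atria some TGF-beta and BMP genes rose, while few or no markers of non-muscle cells passed. Of 22 TGF-beta and BMP pathway genes 4 rose, namely Smad7, the receptor genes Acvr1 (log2 0.49, edgeR adjusted p = 0.017) and Tgfbr1 (0.39), and the BMP target Id1 (0.87), and none fell (7 rose adjusted over the list alone). The list had a median of 0.40 and a camera adjusted p = 0.000525, or adjusted p = 0.657 with an estimated correlation. Fibroblast markers had a median of 0.65 with 1 of 16 higher, Fap (0.79; 2 adjusted over the list alone; camera adjusted p = 0.000352, or adjusted p = 0.711 with an estimated correlation). No extracellular matrix gene of 32 and no macrophage marker of 18 passed, also adjusted over the list alone, with camera adjusted p = 0.0141 and 0.033 towards higher values, or adjusted p = 0.772 and 0.776 with an estimated correlation. These lists were low in a single library: WT LA replicate 3 had a mean of 1.55 log2 CPM over macrophage markers against 3.54 and 3.52 in the other WT LA libraries, 4.67 against 5.62 and 5.83 over fibroblast markers and 3.89 against 4.73 and 5.32 over matrix genes. Without it the camera adjusted p was 0.804 for macrophage markers, 0.894 for matrix genes, and 0.0214 for both the fibroblast and the TGF-beta lists, with 0 and 2 members higher.

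Other lists that passed camera held few changed genes. Dbh, the enzyme that makes noradrenaline (edgeR adjusted p = 0.0197), was among 2 genes that rose of 7 neuronal and Schwann cell markers (3 adjusted over the list alone; camera adjusted p = 0.0095), and Abcc9 among 13 smooth muscle markers (1 adjusted over the list alone; camera adjusted p = 0.0114). Xbp1 (0.47), Edem1 (0.50) and Creld2 (0.52) rose among 17 endoplasmic reticulum chaperone genes (5 adjusted over the list alone; camera adjusted p = 0.0271, and 0.0514 without WT LA replicate 3). Immediate early and heat shock genes had a median of 0.78, although Hsph1 (-0.57) fell and none of 21 rose (1 fell adjusted over the list alone; camera adjusted p = 0.00689). Of 3 adipocyte markers Cox8b (-0.80), also a respiratory chain subunit, and Thrsp (-0.93) fell (2 adjusted over the list alone; camera adjusted p = 0.0217). With an estimated correlation these adjusted p were 0.656, 0.657, 0.753, 0.753 and 0.657 in that order. No list passed with an estimated correlation in any comparison against WT.

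The lists that camera did not call in KO against WT left atria were stress peptides (adjusted p = 0.598; 1 of 12 higher and 1 lower, median -0.02 but mean 0.15), ventricular identity (0.428; Mpped2 fell among 6), vasoactive genes (0.149; Adra1a and Apln rose among 23) and coagulation (0.121; none of 14). The same held for amino acid and stress response genes (0.121; Mthfd2 and Atf5 fell among 19), inflammatory cytokines (0.232; none of 22, median -0.03 but mean 0.16), interferon-stimulated genes (0.124; none of 25) and the circadian clock (0.542; none of 19). It held too for the cell cycle (0.18; none of 23), endothelial markers (0.121; Kdr and Sox18 rose among 16), lymphocyte markers (0.204; none of 12), epicardial markers (0.309; Wt1 rose among 12), skeletal muscle (0.931; none of 5), erythroid (0.581; none of 7) and sex-linked genes (0.336; none of 5, median -0.54 but mean 1.18). Adjusted over the list alone, 5 vasoactive genes were higher and 1 lower, 2 ventricular genes were lower and 1 higher, 1 stress gene was higher and 1 lower, and 2 endothelial genes and 1 epicardial gene were higher. In the left-right and potassium lists camera pointed to lower values although the medians were 0.04 and 0.001, and in the atrial fibrillation list it pointed to higher values although the mean was -0.004. The medians of the atrial, ventricular, calcium, atrial fibrillation and clock lists changed sign without scaling.

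The largest rises among genes of at least 5 CPM were in Mmp9, a matrix metalloproteinase (log2 1.86, SE 0.45, edgeR adjusted p = 0.045), Negr1, a neuronal adhesion molecule (1.31, 0.022), Banp (1.25, 0.0096), the peptide gene Apln (1.20, 0.035), and the transcription factors Rfx2 (1.12, 0.043) and Heyl (1.12, 0.033). Besides those given, the falls included Plet1os (-1.56, edgeR adjusted p = 0.025), which is named as an antisense transcript and is uncertain because the strand used in counting is not given. Ogdhl, Banp, Smad7, Cox7a1, Ndufb9, Hadhb, Hadh, mt-Co2, mt-Atp6 and mt-Co3 passed in all 15 alternatives. Scn4b passed in 14, with adjusted p from 5.8e-09 (DESeq2) to 0.052 (edgeR without KO LA replicate 3), and Camk2b in 14, up to 0.052 without KO LA replicate 1. Hcn2, Nppb and other genes given only as examples were not followed through the alternatives. The other called genes that were named by rule and are given here passed in 7 to 13 and lost the call without 1 library. Their highest values included 0.12 for Mmp9 and Rfx2 and 0.10 for Apln without WT LA replicate 2, 0.097 for Nppa and 0.08 for Pln without KO LA replicate 1, and 0.10 for Heyl without KO LA replicate 3.

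**Figure D2:**
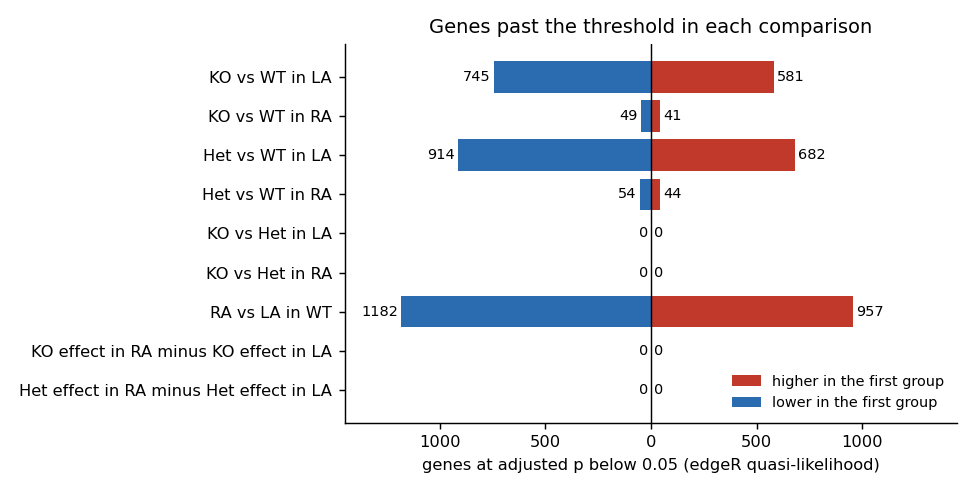
Number of genes past edgeR's test (horizontal axis) in each comparison, with bars to the left for genes lower and to the right for genes higher in the first group named. The LA comparisons with WT have 1326 and 1596 calls and the RA comparisons 90 and 98, while KO against Het has 0 in both atria.

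In the right atrium, the same question for KO against WT gave fewer calls, led by a transcriptional repressor and by respiratory chain genes. Bcl6 (chromosome 16, 23965052 to 23988852), a repressor known from lymphocytes, rose from 8.92 ± 0.447 to 18.4 ± 1.26 CPM (n = 2 and 3; log2 1.05, SE 0.11, edgeR adjusted p = 0.0055). Adam19, a membrane metalloprotease, rose from 52.9 ± 1.09 to 114 ± 13.9 CPM (log2 1.11, edgeR adjusted p = 0.033), and the kinase gene Nrk (1.35, edgeR adjusted p = 0.016), Fam102b (0.93, 0.0055), the neuropeptide Y receptor gene Npy1r (0.82, 0.047) and the Rap exchange factor gene Rapgef5 (0.81, 0.0084) also rose. Scn4b fell by 1.80 (edgeR adjusted p = 0.0162), the pacemaker-region transcription factor Tbx3 by 0.66 (edgeR adjusted p = 0.046) and the activity-regulated gene Arc by 1.38 (edgeR adjusted p = 0.035). Rps29, a ribosomal protein gene, fell by 1.03 (edgeR adjusted p = 0.023). Rps29 has close copies in the genome, so that its counts are uncertain. Bcl6, Fam102b, Rapgef5 and mt-Atp6 passed in 13 of 15 alternatives and the other genes named by rule in 5 to 11. Each had its highest adjusted p without a WT RA library, from 0.095 for Bcl6 to 0.41 for Npy1r without WT RA replicate 3.

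Here 90 of 17201 genes passed edgeR's test, 41 higher and 49 lower, 21 by more than 2-fold (2508 at an unadjusted p under 0.05). All 90 separated the groups, as did 37.2% of all tested genes, against 20% by chance for 3 against 2. Library totals alone gave 98 calls with 61.2% higher, against 45.6% with TMM. Without either WT RA library no gene passed edgeR's test (0 without WT RA replicate 1-2 and 0 without replicate 3), and the count was 10 without KO RA replicate 1 and 9 without KO RA replicate 3. DESeq2 called 387, limma-voom 55, edgeR without a filter 850, with the KO and WT libraries alone 377 and with Xist as a covariate 27.

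Respiratory chain genes fell in KO right atria, 7 of 96 with none higher (22 adjusted over the list alone; median -0.13, camera adjusted p = 3.17e-09, or adjusted p = 0.644 with an estimated correlation). Examples were Cox8b (88.6 ± 0.202 to 60.2 ± 4.67 CPM, log2 -0.56, edgeR adjusted p = 0.016), Atp5o, a subunit of ATP synthase (-0.63, 0.029), and Cox7a1 (-0.49, 0.0333). Of 13 mitochondrially encoded genes 4 fell (7 adjusted over the list alone; camera adjusted p = 7.87e-08, or adjusted p = 0.644 with an estimated correlation): mt-Co2 (-1.51), mt-Atp6 (-1.81), mt-Co3 (-1.36) and mt-Atp8 (-1.72). The first 3 have near-identical nuclear copies, and none of the 6 genes without such a copy passed (median -0.15). mt-Tc, a mitochondrial transfer RNA gene, fell by 1.48 (edgeR adjusted p = 0.016). Cardiomyocyte markers averaged 10.82, 10.94 and 10.84 log2 CPM in KO RA against 10.98 and 11.07 in WT RA, with none of 16 called (5 lower adjusted over the list alone; camera adjusted p = 0.0196, or adjusted p = 0.644 with an estimated correlation).

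Of the other lists in KO right atria, the sodium and pacemaker channel list had Scn4b lower (3 adjusted over the list alone; camera adjusted p = 0.0196), and no fatty acid oxidation gene of 24 passed (2 lower adjusted over the list alone; camera adjusted p = 0.0176). Camera also called interferon-stimulated genes (median -0.36, adjusted p = 0.00184), inflammatory cytokines (-0.38, 0.0176), macrophage markers (-0.24, 0.0196) and epicardial markers (-0.32, 0.0285) towards lower values, with no gene called in any of them. It called endoplasmic reticulum chaperones (0.09, 0.00796), matrix genes (0.20, 0.0285) and immediate early genes (0.22, 0.0285) towards higher values, again with no gene called. Adjusted over the list alone 5 chaperone and 3 immediate early genes were higher and 1 cytokine and 1 macrophage gene lower. With an estimated correlation all of these had adjusted p of 0.644 to 0.71. The TGF-beta list did not pass (camera adjusted p = 0.241; none of 21, and 2 higher and 1 lower adjusted over the list alone).

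Whether a Het genotype changed the left atrium was asked in the same way, with sex fully confounded. The named metabolic and channel genes again stood lower in Het than in WT. Ogdhl (2.95 ± 1.2 CPM, log2 -2.08, edgeR adjusted p = 0.0056), Scn4b (13.5 ± 5.03 CPM, -1.95, 0.016) and Hcn2 (-1.26, 0.00593) fell. The plasma membrane calcium pump gene Atp2b2 fell from 18.8 ± 1.25 to 5.63 ± 0.884 CPM (log2 -1.75, SE 0.24, edgeR adjusted p = 0.0069), and Ryr3, a calcium release channel gene, fell from 16.2 ± 2.84 to 4.3 ± 1.86 CPM (log2 -1.92, edgeR adjusted p = 0.037). The largest rises were in Adamtsl2 (1.99, edgeR adjusted p = 0.047), Scml4 (1.88, 0.037), Fndc1 (1.75, 0.0496), the adhesion gene Lsamp (14.4 ± 1.91 against 4.55 ± 1.52 CPM, 1.64, 0.025), the macrophage lectin gene Mgl2 (1.60, 0.047) and Pdgfrl (1.53, 0.049). Smad7 rose to 29.3 ± 3.64 CPM (0.85, edgeR adjusted p = 0.0056) and Acvr1 by 0.60 (edgeR adjusted p = 0.0077). Adamtsl2, Fndc1, Pdgfrl and Ryr3 passed in 6 of 15 alternatives, Mgl2 in 7, Scml4 and Lsamp in 8, and Adra1a in 7 of 14. Plet1os passed in 10 of 15, and the other called genes named by rule in Het left atria in 12 to 14 of 15.

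In Het against WT left atria 1596 of 16974 genes passed edgeR's test, 682 higher and the rest lower, 194 by more than 2-fold (4568 at an unadjusted p under 0.05). In 1594 of them the groups did not overlap, against 32.3% of all genes and 10% by chance. Library totals alone moved the median by 0.236 and gave 4528 calls with 94.8% higher, against 42.7% with TMM. With Xist as a covariate edgeR called 0 genes, and the named genes then had adjusted p of 0.24 (Smad7) to 0.71 (Ryr3). The count was 832 without WT LA replicate 2, 672 without WT LA replicate 3, 788 without Het LA replicate 1, 307 without Het LA replicate 2, 651 without Het LA replicate 3 and 1037 with the Het and WT libraries alone, and 2786 without a filter.

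Energy genes fell in Het left atria, 47 of 96 in the respiratory chain (78 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.58e-20), 13 of 24 in fatty acid oxidation (15; 1.42e-08) and 9 of 13 mitochondrially encoded genes (13; 1.31e-09). Cox7a1 (159 ± 5 CPM, log2 -0.58, edgeR adjusted p = 0.0056), Ndufb8 (-0.55, 0.0056), Hadh (-0.59, 0.0056), Acads (-0.74, 0.0056) and the mitochondrial creatine kinase gene Ckmt2 (560 ± 14 against 919 ± 122 CPM, -0.71, 0.0056) are examples. All 6 mitochondrial genes without a near-identical nuclear copy fell, among them mt-Nd1 (29000 ± 2490 to 18100 ± 340 CPM, log2 -0.68, edgeR adjusted p = 0.0059) and mt-Nd6 (-0.85, 0.0056). In glycolysis 8 of 20 fell, such as Pdk1 (-0.44), and Pfkp rose (0.37; 14 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.82e-05). Cardiomyocyte markers had 5 of 16 lower (9 adjusted over the list alone; camera adjusted p = 9.82e-06), and averaged 10.95, 10.96 and 11.04 log2 CPM against 11.22, 11.28 and 11.45 in WT. With an estimated correlation each of these lists had adjusted p = 0.506. Without WT LA replicate 3 the lower calls were 16 in the respiratory chain, 6 in fatty acid oxidation and 8 among mitochondrially encoded genes.

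Among contractile and channel genes in Het left atria, the sarcomere list had 5 of 26 lower (14 adjusted over the list alone; camera adjusted p = 9.82e-06), including Mybpc3 (1830 ± 194 to 1180 ± 131 CPM, log2 -0.63, edgeR adjusted p = 0.01) and Ttn (-0.48, 0.018). Of 28 calcium genes 7 fell, such as Cacna2d2 (-0.45, edgeR adjusted p = 0.013) and Cacna1c (-0.48, 0.016), and Atp2b4 and Itpr1 rose (6 higher and 16 lower adjusted over the list alone; camera adjusted p = 0.00859). The sodium and pacemaker list had 3 of 11 lower, among them Scn4b and Hcn2 (4 adjusted over the list alone; camera adjusted p = 0.0188). These 3 lists had adjusted p = 0.506 with an estimated correlation. Of 24 potassium channel genes 5 fell, such as Kcnj2 (-0.37, edgeR adjusted p = 0.016), and Abcc9 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.529). Nos3 (0.56, edgeR adjusted p = 0.019) and Adra1a (2.15, 0.035, under 1 CPM in both groups) were among 5 of 23 vasoactive genes that rose (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.128).

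In Het left atria some TGF-beta genes and fibroblast markers rose. In the TGF-beta list Smad7, Acvr1, Tgfbr1 (0.48), Tgfb1 (0.50), Inhbb (edgeR adjusted p = 0.0381) and Id3 (0.62) rose, 6 of 22 (8 adjusted over the list alone; camera adjusted p = 0.000144, or adjusted p = 0.506 with an estimated correlation). Fibroblast markers had Fap (0.81), Tcf21 (1.07) and Smoc2 (1.20) higher, 3 of 16 (5 adjusted over the list alone; camera adjusted p = 2.32e-05, or adjusted p = 0.506 with an estimated correlation). No matrix gene of 32 and no macrophage marker of 18 passed, also adjusted over the list alone (camera adjusted p = 0.000464 and 0.00275, or adjusted p = 0.655 and 0.695 with an estimated correlation). Interferon-stimulated genes (Ddx58 rose among 25, none adjusted over the list alone; camera adjusted p = 0.000432), immediate early genes (Myc rose and Hsph1 fell among 21, 3 and 1 adjusted over the list alone; 0.000767), endothelial markers (Kdr rose among 16, 1 adjusted over the list alone; 0.0116) and the cell cycle (Mcm4 and Mcm6 rose among 23, 3 adjusted over the list alone; 0.0113) passed camera, with adjusted p of 0.604 to 0.702 with an estimated correlation. Het LA replicate 2 stood highest in immediate early genes (4.99 log2 CPM) and interferon-stimulated genes (3.89). Without WT LA replicate 3, the library low in non-muscle markers, the camera adjusted p was 0.122 for matrix genes, 0.171 for macrophage markers, 0.0914 for endothelial markers and 0.122 for the cell cycle. The sex-linked list had no gene called (1 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0357, or adjusted p = 0.506 with an estimated correlation). Xist and Ddx3y nevertheless separated Het from WT fully. The fit shares its spread with KO, which holds both sex patterns, so genes that differ by sex have a wide spread and can miss the call. The lack of calls is therefore no sign that such genes were alike in Het and WT.

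In Het against WT right atria the leading change was again Bcl6, which rose from 8.92 ± 0.447 to 20.8 ± 1.25 CPM (n = 2 and 3; log2 1.22, SE 0.11, edgeR adjusted p = 0.0017). Nrk (1.24, edgeR adjusted p = 0.028), the guidance factor gene Slit2 (0.98, 0.028), Heyl (0.79, 0.037) and Tmem45a (0.85, 0.0489) rose. Syn2, a synapsin gene, fell from 15.1 ± 0.272 to 5.79 ± 1.46 CPM (log2 -1.38, edgeR adjusted p = 0.025), Arc by 1.31 (edgeR adjusted p = 0.046) and the stress gene Ankrd1 by 0.99 (edgeR adjusted p = 0.0439). In the respiratory chain Ndufa3 (-0.48, edgeR adjusted p = 0.025) and Atp5o (-0.57, 0.043) were among 3 of 96 lower genes (24 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.81e-12). Of 13 mitochondrially encoded genes 7 fell (12 adjusted over the list alone; camera adjusted p = 2.17e-12), of which mt-Co2 (-1.45), mt-Atp6 (-1.45), mt-Co3 (-1.25), mt-Nd3 (-1.35) and mt-Nd4l (-2.26) have near-identical nuclear copies and are uncertain; mt-Nd6 (-0.63, edgeR adjusted p = 0.0489) has none. mt-Atp8 (-1.26) was placed in neither group, and mt-Tc (edgeR adjusted p = 0.025) fell too. Both lists had adjusted p = 0.372 with an estimated correlation. Bcl6 passed in 13 of 15 alternatives (highest edgeR adjusted p = 0.13, without WT RA replicate 3) and the other genes named by rule in 6 to 12.

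There 98 of 17201 genes passed edgeR's test, 44 higher and 54 lower, 20 by more than 2-fold (2458 at an unadjusted p under 0.05). All 98 separated the groups, as did 33.2% of all genes, against 20% by chance. The share of higher calls was 44.9% with TMM, 27.7% with upper-quartile scaling and 78.7% of 221 calls with library totals alone, which moved the median by 0.101. Without WT RA replicate 1-2 the count was 2, without WT RA replicate 3 it was 0, and without Het RA replicates 1, 2 and 3 it was 31, 47 and 33. With Xist as a covariate edgeR called 0 genes, while DESeq2 called 406, limma-voom 38, edgeR without a filter 892, with all libraries 51 and with corrections for GC content and length 160.

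Contractile lists stood lower in Het right atria, with Mybpc3 (-0.43) called among 26 sarcomere genes (5 lower adjusted over the list alone; camera adjusted p = 3.41e-06) and Mybpc3 and Ckmt2 (-0.65) among 16 cardiomyocyte markers (5; 1.2e-05). Those markers averaged 10.68, 10.81 and 10.8 log2 CPM, against 10.98 and 11.07 in WT RA. The sodium and pacemaker list had 1 of 11 lower (3 adjusted over the list alone; camera adjusted p = 0.00248). Left-right identity (2 lower and 1 higher adjusted over the list alone; 0.0322), calcium (3 and 1; 0.0322), atrial identity (1 lower; 0.0333), fatty acid oxidation (5 lower; 0.00355) and glycolysis genes (none; 0.00355) passed camera towards lower values with none called. Fibroblast markers (7 higher adjusted over the list alone; camera adjusted p = 0.00154), matrix genes (11 higher and 3 lower; 0.00201), chaperones (5 higher; 0.0166), coagulation genes (none; 0.0348) and the cell cycle (none; 0.038) passed towards higher values with none called. With an estimated correlation their adjusted p lay between 0.372 and 0.746. Adipocyte markers had a median of 0.10 and a mean of 0.90 although camera pointed to lower values (adjusted p = 0.577). Sex-linked genes passed camera too (adjusted p = 0.026, or adjusted p = 0.372 with an estimated correlation), with none called. The spread shared with KO limits these calls as it does in LA.

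KO against Het asks whether the groups differed from each other, and no gene passed edgeR's test in either atrium. In LA there were 0 of 16974 (771 at an unadjusted p under 0.05; smallest edgeR adjusted p = 0.295), with 13 by DESeq2, 0 by limma-voom and 103 without a filter. In RA there were 0 of 17201 (1077 at an unadjusted p under 0.05; smallest edgeR adjusted p = 0.431), with 16 by DESeq2, 0 by limma-voom and 210 without a filter. Cox7a1 was at 142 ± 10.3 and 159 ± 5 CPM in KO and Het LA (edgeR adjusted p = 0.974), Bcl6 at 18.3 ± 1.94 and 21.2 ± 1.28 CPM (0.974) and mt-Nd1 at 20280 ± 1520 and 18140 ± 340 CPM (0.974). In RA Nppb was at 261 ± 25.4 and 175 ± 22.8 CPM (edgeR adjusted p = 0.778), and the clock gene Cry1 at 14.2 ± 1.39 and 8.99 ± 1.1 CPM (0.647). Without KO replicate 1, the KO animal with a female pattern, edgeR called 14 genes in LA and 15 in RA.

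Calls against WT were shared between KO and Het. In LA 375 genes were higher in both and 522 lower in both, with none in opposite directions, where independent lists would share 23.3 and 40.1. In RA 18 and 29 were shared, against 0.105 and 0.154. Both genotypes were compared with the same WT libraries, and 20 simulations of unchanged groups against these shared at most 0 higher and 1 lower gene in LA and 2 and 1 in RA. Few genes can pass when groups are unchanged, so these counts are no reference for the sharing seen. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.727 in LA and 0.627 in RA, where the simulations gave means of 0.533 and 0.636. The covariance was 0.144 against a simulated 0.0411 in LA, a difference of 0.103, and 0.103 against 0.0618 in RA, a difference of 0.0412. The WT libraries were too few to divide, so part of the excess may come from the shared controls. Between atria, which share animals but no libraries, KO calls shared 33 higher and 40 lower genes (independent lists 1.43 and 2.14) and Het calls 34 and 33 (1.8 and 2.95).

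**Figure D3:**
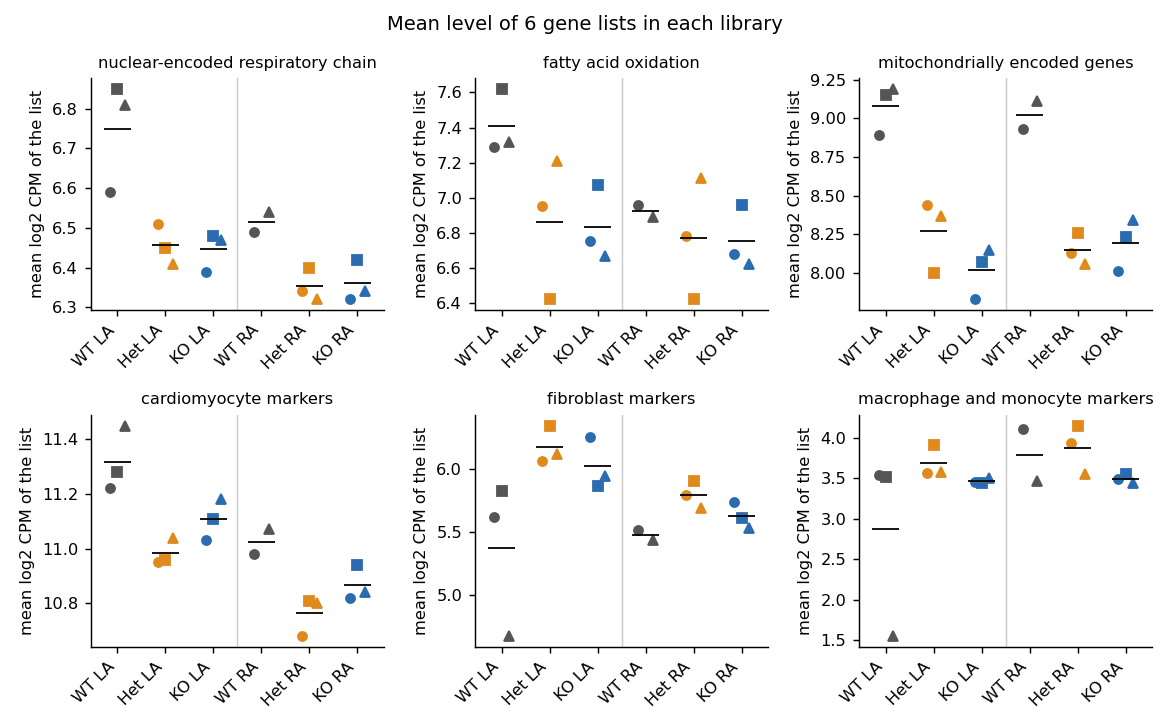
Mean log2 CPM of 6 gene lists (vertical axes) in each library by group, with marker shape for the replicate, colour for the genotype and a bar at each group mean. Respiratory chain and fatty acid oxidation means lie highest in WT LA, and WT LA replicate 3 lies at 1.55 over macrophage markers where the other LA libraries lie between 3.44 and 3.91.

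The atria of WT animals were compared to describe chamber differences without a genotype effect. Bmp10 (chromosome 6, 87428994 to 87437677), a BMP ligand of the right atrium, was at 8250 ± 809 CPM in RA and 2.69 ± 1.53 CPM in LA (n = 2 and 3; log2 11.50, SE 0.47, edgeR adjusted p = 2.3e-08). The hepcidin gene Hamp (7.69, edgeR adjusted p = 3.7e-06), A2m (7.48, 1.6e-08), the Langerhans cell lectin gene Cd207 (7.44, 1.9e-05), the chemokine gene Cxcl13 (5.01, 4e-06), Efnb3 (4.57, 5.6e-08) and the adrenomedullin gene Adm (4.44, 1.2e-07) were higher in RA. Hmcn2 (-6.75, edgeR adjusted p = 7.5e-08), Timp4 (-4.42, 0.00049), Scara5 (-4.09, 1.9e-05), Cpne7 (-3.43, 0.0089), Scn4b (-3.37, 5.45e-05) and the neuronal nitric oxide synthase gene Nos1 (-2.59, 0.00025) were lower.

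Of 18018 genes 2139 passed edgeR's test between WT atria, 957 higher and 1182 lower in RA, 656 by more than 2-fold (4529 at an unadjusted p under 0.05), and 2135 of them separated the groups, against 41.6% of all genes and 20% by chance. The fit with the animal as a block, which pairs the atria, called 3351 (1721 higher and 1630 lower). The count was 1193 with the WT libraries alone, and 3351 became 3901 when the identical library was taken as animal 2. Leaving out WT replicate 1 or 2 drops the same WT RA library, so every fit without a WT replicate keeps 1 WT RA library. Of the named genes, Cpne7, Eno3, Pgam2, Myoz2 and Actc1 lost the call in the fit without WT replicate 2, which does not single out that animal. Over all alternatives the log2 change was -3.61 to -3.27 for Cpne7 and -0.75 to -0.44 for Actc1. The same comparison gave 1386 calls in Het (599 higher and 787 lower) and 1504 in KO (660 and 844).

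In WT right atria, genes of left-right and pacemaker identity rose, 7 of 13, including Bmp10, Hamp, Cacna2d2 (257 ± 30.4 against 19.6 ± 0.444 CPM, log2 3.71, edgeR adjusted p = 1.3e-08), Shox2 (edgeR adjusted p = 0.0135) and Tbx3 (0.56, 0.00418), and 1 was lower (9 and 3 adjusted over the list alone). This list had a camera adjusted p = 1.94e-05, or adjusted p = 0.0504 with an estimated correlation. In RA against LA of the Het animals the same list had an adjusted p = 0.0341 with an estimated correlation, and in the KO animals 0.107. TGF-beta and BMP genes had 8 of 23 higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.000237, or adjusted p = 0.543 with an estimated correlation), among them Bmp10, Smad7 (57 ± 0.937 against 16.7 ± 1.37 CPM, log2 1.77, edgeR adjusted p = 4.5e-08), Smad6 (2.38), Id1 (1.82), Id2 (1.80) and Id3 (1.65). Macrophage markers had 4 of 19 higher (5 adjusted over the list alone; camera adjusted p = 0.000264, or adjusted p = 0.751 with an estimated correlation), with WT LA replicate 3 low in these markers. Of 8 neuronal markers 3 rose, led by Dbh (4.56; 6 adjusted over the list alone; camera adjusted p = 0.000651, or adjusted p = 0.191 with an estimated correlation). The endothelial (3 of 16 higher; 7 and 1 lower adjusted over the list alone; 0.0268), cell cycle (3 of 23, and 3; 0.0268) and interferon lists (none of 25, and none; 0.0498) passed camera too, with adjusted p of 0.751 to 0.821 with an estimated correlation.

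Energy and contractile genes were lower in WT right than left atria. In the respiratory chain 67 of 97 fell and 1 rose (79 and 2 adjusted over the list alone; camera adjusted p = 4.28e-27), for example Sdhb (440 ± 48.7 to 289 ± 5.55 CPM, log2 -0.61, edgeR adjusted p = 0.00014) and Ndufa10 (-0.50, 0.00027). Of 24 fatty acid oxidation genes 14 fell (16 adjusted over the list alone; camera adjusted p = 2.53e-09), such as Fabp3 (-0.80, edgeR adjusted p = 0.00029) and Acadm (-0.56, 0.0016), and 5 of 13 mitochondrially encoded genes (7 adjusted over the list alone; camera adjusted p = 0.0203). The sarcomere list had 7 of 26 lower (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 4.9e-06), such as Myoz2 (-0.92) and Actc1 (-0.62), and cardiomyocyte markers 7 of 16 (10 adjusted over the list alone; camera adjusted p = 2.66e-06), at 10.98 and 11.07 log2 CPM in RA against 11.22 to 11.45 in LA. With an estimated correlation these 5 lists had adjusted p of 0.356 to 0.751. In glycolysis Eno3 (-0.76) and Pgam2 (-0.58) were among 6 of 20 lower and Slc2a1 and Pfkp rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0166, or adjusted p = 0.751 with an estimated correlation). The animal block ended this call (0.0882), and the list's median of -0.16 turned to 0.01 without scaling. With the block camera also called matrix genes (0.00805), inflammatory cytokines (0.0488) and lymphocyte markers (0.0448). Between atria of Het and of KO animals, 35 and 23 of 97 respiratory chain genes were lower and 1 was higher in each. There 3 of 24 fatty acid oxidation genes were lower in each, and no mitochondrially encoded gene was called. Sarcomere genes had 7 and 8 lower (1 higher in Het), and cardiomyocyte markers 7 lower in each.

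Other WT chamber differences went both ways within a list. Of 28 calcium genes 6 were higher and 8 lower in RA (8 and 12 adjusted over the list alone; camera adjusted p = 0.395), among them Hrc (-0.63, edgeR adjusted p = 9.9e-05). Of 34 genes at atrial fibrillation loci 4 were higher and 6 lower (5 and 8 adjusted over the list alone; camera adjusted p = 0.42), such as Cav1 (-0.75, edgeR adjusted p = 1.7e-05). Of 24 cardiac transcription factors 5 were higher, such as Hey1 (1.64, edgeR adjusted p = 9.9e-06), and 2 lower (7 and 4 adjusted over the list alone; camera adjusted p = 0.371). In the atrial identity, calcium, transcription factor, atrial fibrillation, vasoactive and fibroblast lists the median and mean differed in sign.

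A difference of the genotype effect between atria was tested directly, since fewer calls in RA, with 1 library less, do not show one. No gene passed edgeR's test for the KO effect in RA minus that in LA (0 of 18018; 711 at an unadjusted p under 0.05; smallest edgeR adjusted p = 0.995; 1 by DESeq2, 0 by limma-voom, 140 without a filter) or for the Het effect (0; 786; 0.82; 1 by DESeq2, 0 by limma-voom, 163 without a filter). With the animal as a block, which pairs the atria, 8 genes passed for KO and 21 for Het. Smad7, Smad6 and Id3 were among both, which share the WT libraries. For Smad7 the KO effect was 0.73 lower in RA than in LA on the log2 scale in that fit (-0.73, edgeR adjusted p = 0.022) and the Het effect 0.83 lower (-0.83, edgeR adjusted p = 0.0068). In RA Smad7 itself did not pass in KO (0.26, edgeR adjusted p = 0.239) or in Het (0.08, edgeR adjusted p = 0.753). Camera called some lists for the KO interaction without the block. Towards higher values these included the respiratory chain (adjusted p = 9.88e-14) and fatty acid oxidation (3.3e-07). Interferon-stimulated genes (7.27e-06) were among those towards lower values. With an estimated correlation each of these had an adjusted p = 0.53.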

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

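Among the tests below, those of nuclear copies, of GC content and length, of the share of cardiomyocytes, of KO left atria without the female animal, of ribosomal RNA and of clock genes against sex were chosen after the result was seen, and the others were chosen before. In the fit with the animal as a block, which pairs the atria, the effect of KO differed between RA and LA in 8 genes and that of Het in 21, and this difference between atria is why they stand here. For KO these were Smad7 (-0.73, edgeR adjusted p = 0.022), Smad6 (-1.03, 0.029), Id3 (-0.80, 0.016), Actb (-0.65, 0.02), Adcy7 (-1.23, 0.016), Cap1 (-0.58, 0.033), Elf4 (-0.87, 0.033) and 1 ID without a symbol. For Het they included Smad7 (-0.83, 0.0068), Smad6 (-1.06, 0.014), Id3 (-0.77, 0.0083), Skil (-0.54, 0.02), Klf2 (-0.68, 0.04) and Gata2 (-0.59, 0.031), all lower, with Zfp970 (0.58, 0.035) and Aldh1l2 (0.51, 0.033) higher. Smad6, Smad7 and Id3 respond to BMP signals, and all 3 are higher in WT RA than in WT LA. The KO and Het contrasts both subtract that same difference between WT atria. Calls in both contrasts and a higher level in WT RA are therefore not separate evidence. Without the block no gene passed. With the identical library taken as WT animal 2 in the block, 98 and 154 genes passed, including 5 of the 8 and 11 of the 21, while Smad6 did not (edgeR adjusted p = 0.1 and 0.086). Of the other genes named, Adcy7 (0.2) and Elf4 (0.057) lost the call for KO, and Klf2 (0.83) for Het.

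The first pattern weighed is that WT left atria stand apart from both Het and KO. Genotype is the biological explanation, and sex, carry-over of ribosomal RNA, gene composition and a single library are the technical ones tested. Without KO LA replicate 1 the KO and WT libraries are all of a male pattern, and 334 genes were still called in KO against WT in LA, so sex is not the whole cause in KO. In Het against WT alone, sex cannot be told apart from genotype. Over 1504 autosomal genes called in Het in LA, the 2 male KO right atria showed a mean of 0.721 of the Het change in RA (0.686 and 0.756). The 1 female KO right atrium showed 0.928, nearer to the Het right atria (0.969 to 1.02). The KO and Het changes are measured from the same WT libraries, so such a share can arise without an effect of KO. Without KO LA replicate 1, KO (male pattern) against Het (female pattern) gave 14 calls in LA. Het against WT in LA gave 672 to 1742 with 1 WT library left out. If sex alone set Het apart from WT, the KO effect would have to match the sex effect across these genes. Such a match need not be close, since with 2 KO libraries small differences can be missed. The fits of Het against WT also kept both sex patterns in KO, which widens the spread of genes that differ by sex. The fit of KO against Het did not. These counts thus cannot decide whether sex is all of the Het difference in LA. Sex may account for part of the difference in Het and in KO. An ID that resembles 18S ribosomal RNA held 1.68 to 2.52% of counts in WT LA against 0.53 to 1.49% in Het and 0.89 to 1.32% in KO. Within the LA groups the score along the KO change followed this share with 0.0493 of the slope between WT and KO (95% limits -0.248 to 0.346). The score was built from the genes called in KO against WT in LA, which were picked for little spread within groups. That choice favours a small slope, so the test cannot decide on carry-over of this RNA. A batch or RNA preparation that sets WT apart, which this share may mark, stays open too. So does the time of day at collection, which is taken up with the clock genes below. After correction for GC content and transcript length 1285 genes were called in LA against 1326 without it, with 1059 in both. That speaks against such a bias as the whole cause, yet the called genes differed in both traits. Median transcript length was 4678 bases in genes called higher, 2653 in those called lower and 3098 in those not called. Their median GC content was 46.5, 50.1 and 49.2% in that order. Without WT LA replicate 3 the count was 480, which leaves the part of that library open.

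Of the 10 ways to divide 6 libraries into 3 and 3, only the real one (1 of 10) gave as many calls for KO against WT in LA (1326, highest other 0) and for Het against WT in LA (1596, highest other 0). For KO against Het, 10 of 10 gave as many in LA (0, highest other 0) and 10 of 10 in RA (0, highest other 1). With 10 splits the share cannot go under 0.05. A batch shared by the WT animals could not be tested, since the labels give none.

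The next pattern is the fall of mitochondrial and respiratory chain genes in KO left atria. In mitochondrially encoded genes without a near-identical nuclear copy the median change was -0.54. Reads shared with near-identical copies among annotated transcripts could not produce this change. That value leaves open whether all mitochondrial transcripts fell alike, since genes with such a copy had a median of -1.96, and at 0.475 to 9.26 CPM reads shared with the copies may set their counts. Relative to cardiomyocyte markers the genes without a copy still stood lower in KO (-0.35). As far as these markers, some of them called lower themselves, track the share of cardiomyocytes, a lower share would not account for them alone. The nuclear-encoded chain did not stand lower (-0.09), so fewer cardiomyocytes, or fewer of their transcripts, may account for its fall. Fatty acid oxidation genes had -0.37, but KO (-4.515 to -4.04) and WT libraries (-4.124 to -3.657) overlapped, which leaves them open.

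The last pattern is in the clock genes of KO replicate 1. Mean clock output was 4.56 log2 CPM in its LA and 4.60 in its RA, where the other libraries lay between 5.44 and 6.46. Collection at another time of day would move Arntl, Npas2 and Clock opposite to Dbp and Per3, and 6 of 6 values did so, for example Arntl by 1.9 and Dbp by -2.02 in LA. The female Het animals moved the same way to a smaller extent: in Arntl, Npas2, Clock, Dbp and Per3 all Het libraries lay between the WT libraries and KO replicate 1, in both atria. In RA Arntl was at 4.42 to 4.60 log2 CPM in Het and 4.54 in KO replicate 3, against 3.28 and 3.24 in WT and 2.58 in KO replicate 2. In mean clock output 6 of 6 Het libraries lay nearer the WT mean than KO replicate 1, but in single genes not all did, so sex of the animals cannot be told apart here. In LA, too, Arntl was higher in KO replicate 3 (4.43 log2 CPM) than in WT (3.25 to 4.07), while its Per3 (5.72) lay within the WT range (5.42 to 6.27). WT may thus differ in time of day at collection from Het and from some KO animals, which would touch both comparisons with WT. Collection times are not given in the sources used here, and no biological explanation was tested.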

How the results depend on the processing

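The identical columns as 2 libraries, the offsets for GC content and length, and the block with the identical library as WT animal 2 were chosen after the results were seen. Of 127 alternative counts of called genes 65 stayed within 1.5 times the original and 62 did not; of 1717 values for named genes 1373 kept direction and side of the threshold, 344 lost the call and 0 reversed. Of 555 list tests 404 kept their call, 137 lost it and 14 gained it. In the order KO and Het against WT in LA, then in RA, no filter gave 2350, 2786, 850 and 892, Xist as a covariate 542, 0, 27 and 0, and leaving out 1 library 249 to 1475, 307 to 1742, 0 to 77 and 0 to 47. Only the genotypes compared gave 662, 1037 and, for KO in RA, 377, and all libraries in 1 fit 2016 for KO in LA and 51 for Het in RA. In RA DESeq2 gave 387 and 406, limma-voom 55 and 38, and the identical columns as 2 libraries 909 and 737, and offsets for GC content and length 160 for Het. For KO against Het, DESeq2 gave 13 in LA and 16 in RA, no filter 103 and 210, and leaving out 1 library 0 to 14 and 0 to 15.

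For RA against LA in WT, the replicate block gave 3351, the block with the identical library as WT animal 2 3901, only the WT libraries 1193, the identical columns as 2 libraries 3560, and leaving out 1 animal 489 to 774. For the interactions in KO and Het, DESeq2 gave 1 and 1, no filter 140 and 163, the block 8 and 21, the block with the other animal 98 and 154, and leaving out 1 animal 0 to 1 and 0 to 0. Beyond these counts and 4 lists, the block of the animals changed no other call for RA against LA in WT. The lists between atria of Het and KO and those of the interactions were not tested with the block. Animals of different genotypes share only a number (correlations -0.117 to 0.155), and that block gave 152 calls for Het in RA. The Xist covariate takes up most of the Het contrast by construction, and leaving out a library lowers n; for the other changes the cause was not tested. On simulated data 35.2% of 1.5-fold changes were found in KO against WT in LA and 39.4% in RA, so small changes can be missed.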

Other observations

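Adam19 and Bcl6, which rose in KO right atria, also rose in KO left atria (Adam19 1.05, edgeR adjusted p = 0.00191; Bcl6 0.85, 0.0123), and Bcl6 rose in Het left atria (1.06, 0.0056). Phldb2 rose in KO in both atria (0.54 in LA, 0.51 in RA), as did the calcium pump gene Atp2b4 (0.90 and 0.69). Scn4b fell in KO in both atria, from very different levels in WT (51.9 CPM in LA, 5.31 in RA). Lrtm1, a heart-expressed gene, fell in Het left atria (-1.35, edgeR adjusted p = 0.0022), where it stood at 24.1 ± 4.55 CPM against 45.1 ± 2.92 in KO (edgeR adjusted p = 0.301).

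Both hypotheses here had their tests chosen before the result was seen. If the Zfhx3 allele carried a flanking segment from another strain, calls would gather near the gene. Within 10 Mb 11 of 155 genes were called in KO left atria, 7.1% against 7.81% of other autosomal genes (Fisher exact p = 0.88), so such a segment is not likely to explain the calls. The 11 include Ldhd (-0.71), Pdp2 (-0.68) and Pdpr (-0.39), which act in mitochondrial metabolism.

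Since Scn4b, Ogdhl and respiratory chain genes are also lower in RA than in LA of WT animals, KO left atria may have moved towards the right atrial profile. A score from 599 genes higher and 787 lower in RA of Het animals was 0.16 higher in KO LA (-1.61 ± 0.02) than in WT LA (-1.77 ± 0.07), against 2.1 between WT atria. Het LA stood at -1.65 ± 0.03 and Het RA at 0.54 ± 0.02. The Het libraries chose the genes of the score, so their own scores are partly set by that choice and are no separate evidence. The score was also higher in KO RA (0.42 ± 0.02) than in WT RA (0.33 ± 0.06). Bmp10 did not change in KO LA, and cell makeup was not separated. The shift is thus a hypothesis and small beside the difference between atria.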
